A study of Drosophila melanogaster with 3 samples.

How the data were processed

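ChIP-seq of GFP-tagged Pif1A was done on whole pupae in 3 biological replicates, per the labels. The deposited lists are narrowPeak tables on dm6 and on dm3, 5 on each build: 1 for each replicate, 1 for the pooled replicates, and the optimal list from the irreproducible discovery rate (IDR) procedure. Per the deposited file descriptions, the replicate and pooled lists are peaks and background made as input for IDR from the alignments and a control shared by all replicates, and the optimal list derives from them. The aligner, the peak caller, the IDR threshold and the treatment of reads with several placements are not given in the sources used here. The score of each peak is the signal value the authors deposited. Its scale depends on the list, so it was used to rank, describe and filter peaks within a list. The 1 exception is in the section on flagged peaks, where the highest scores of replicate 1 are described on both builds beside their ranks. The −log10 q-value of each peak was also deposited; it reaches the same highest value of 3.86 in 3657 peaks of the pooled dm6 list, and so was not used for ranking. The summit is the deposited offset from the start of the peak. The lists hold no read counts, so depth is unknown and no count model was used. A list of input to IDR holds peaks down to background by construction, so its 30000 entries are not a number of binding sites. As many of the highest peaks were taken from each replicate as the optimal list holds (7283, N below). The optimal dm6 list was found to be the 7283 highest peaks of the pooled list. Overlapping peaks were kept as deposited, and the 7283 peaks merge into 6892 regions.

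Positions are on dm6 (BDGP Release 6), 1-based, and the annotation was Ensembl release 115, on the same assembly, without transposable elements and pseudogenes. A TSS is the start of any annotated transcript. Each summit was placed in the first class that held: within 500 bp of a TSS, 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic. Shares were set against 1000 shuffles of the positions within arms, avoiding unsequenced bases, by two-sided permutation tests. Replicates were compared by the share of the N highest peaks that overlap by 50% of both lengths, against 100 within-chromosome shuffles for each pair. Peaks outside the arms were left out of every comparison but this one and the counts of peaks. Ranks of a named peak in a replicate were taken from the best peak with a summit within 100 bp. Arm shares were tested with exact binomial tests, with Y among the 7 arms; its own test is void, since none of the lists holds a peak on Y. A gene was called bound when an optimal summit lay within 500 bp of one of its TSSs, and each of 20 gene lists and 6 noncoding classes was tested with Fisher's exact test. For 10 listed symbols the current symbol was used, and no listed symbol was left unmatched. Motifs were searched on both strands within 50 bp of the summit and in a window of the same length 400 bp to the left, with exact McNemar tests. Adjusted p-values are Benjamini-Hochberg values over the members of each family (7 classes, 7 arms, 20 lists, 6 noncoding classes, 20 motifs), and tests are two-sided. Genes and peaks are not independent replicates, so a rotation of bound status along gene order (10000 rotations) was an alternative for the lists. Means ± SD over n = 3 are over the N highest peaks of each replicate, except those of the 10 rank bins, which use the whole lists. For optimal peaks, leaving out a replicate means keeping those matched in the other 2, by 50% overlap or, as an added alternative, by summits within 100 bp. The replicates share a control, so their agreement includes what that control contributes, and the optimal list was made from the replicates it is compared with.

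The genes named were set by a rule: those within 500 bp of the 20 highest optimal peaks found in all 3 replicates; in each list the 4 bound members with the highest peak, and up to 2 members without a peak in lists bound less often than all genes; Pif1A, Eip63E and CycY; and the gene holding or nearest to each of the 10 highest peaks over 2000 bp from every TSS. EcR, br, Eip74EF, ftz-f1, the steroid synthesis and metabolism genes, ush, CG11050 and the genes of the closing section that lie outside this rule were chosen after their values were seen. The groups, tests, gene lists, motifs, this rule and 62 alternatives were fixed before the data were examined. The alternatives changed the overlap rule, the number of peaks, the build, the TSS window, the gene assignment, the background, the motif control and the replicates used.

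The steps were tested on simulated data. With 3 lists bound at 45% among 13968 genes bound at 14%, 88.3% of planted lists and 0.882% of other lists were called. Where 60.3% of 7283 peaks had been kept in a copy, 61.3% were found shared. Kept peaks had unchanged widths and were moved little, whereas widths differed between the optimal and replicate lists. The overlap step was thus not tested for unequal widths. Of random summit sets, 2% passed the shuffle test. A motif planted in simulated windows was called in 100% of rounds, and other motifs in 0.526% of cases. Both simulated windows had the same base composition, whereas GC content was 34.6% at optimal summits and 44.0% at 400 bp to the left. Bound genes were drawn independently, unlike neighbouring genes in clusters. These rates of false calls may therefore not hold for the data. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.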

Results

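Pif1A, a protein named as an interaction partner of the PFTAIRE cyclin-dependent kinase Eip63E, was profiled by ChIP-seq in whole Drosophila melanogaster pupae of mixed sex. The flies were a transgenic line with GFP fused to the C terminus of Pif1A, and the tagged protein was recovered with an antibody against GFP from chromatin sonicated to 200 to 800 bp. The series holds 1 group of 3 biological replicates, so the comparisons are between replicates, between peaks and the rest of the genome, and between groups of genes. No sample of flies without the tag is in the series. Signal that does not depend on Pif1A could therefore not be told apart from binding here. Each replicate has a list of 30000 ranked peaks on dm6, the pooled reads have another of 30000, and the authors' optimal list from the irreproducible discovery rate (IDR) procedure has 7283, which are the 7283 highest of the pooled list. The score of a peak is the authors' signal value and is used to rank peaks within a list. Read depth is unknown from these lists.

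The first question was whether the replicates placed their strongest peaks at the same sites. The strongest peak in the optimal list and in each of the 3 replicates lay at Ugalt, which encodes a UDP-galactose transporter (X, peak 2703681 to 2704110, score 2980, summit 35 bp from the TSS). Peaks at the promoters of larp (score 2486), CG14100 (2476) and PNPase (2433), the gene of a mitochondrial RNA-processing enzyme, ranked 2, 4 and 6 in the optimal list and no lower than 6 in any replicate. Ranks 3 and 5 were peaks in introns of ush (2L, 480863 to 481316, score 2482) and CG11050 (2L, 2464). Among the 7283 highest peaks of each replicate, 68.1% ± 1.69 (SD over the 3 pairs) overlapped a peak of the other replicate by at least 50% of both lengths. Shuffling positions within chromosomes gave 1.79% on average, and each pair lay above all 100 of its shuffles (two-sided permutation p = 0.020, the smallest they can give). Scores of matched peaks correlated across peaks with a Spearman rho of 0.698 to 0.760; peaks are not independent replicates.

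Of the 7283 optimal peaks, 3283 (45.1%) were matched among the 7283 highest peaks of all 3 replicates, 2172 in 2, 962 in 1 and 866 in none. Peak width entered this count. Of the 866 peaks matched in none, 799 were narrower or wider than the most common width of 424 bp, with a median width of 237 bp for all 2535 such peaks, whereas the median width in the replicate lists was 400 to 410 bp. With an overlap of 1 bp, 4776 peaks were found in all 3 replicates and 57 in none.

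At the level of the genome, promoters and introns carried most summits and coding exons almost none. Summits within 500 bp of an annotated TSS made up 31.2% of the optimal list against 13.4% of shuffled positions, a 2.32-fold excess, and 34.0% ± 2.43 (SD, n = 3) of the replicates' highest peaks. Introns held 48.1% of summits against 39.5% of shuffled positions, and intergenic sequence 18.1% against 27.4%. Coding exons away from a TSS held 11 summits, 0.151% of the list against 13.7% of shuffled positions, and 0.133% ± 0.0286 (SD, n = 3) in the replicates. 3' UTRs were also low, at 0.700% against 4.46%, while other exons, neither UTR nor coding, were at 1.04% against 0.760%. These 6 classes passed the permutation test over 1000 shuffles after Benjamini-Hochberg adjustment (unadjusted p = 0.0020, the smallest they can give, and adjusted p = 0.0028 for all but other exons, 0.014), and 5' UTRs did not (0.741% against 0.782%, adjusted p = 0.743). The shuffles avoided only unsequenced bases, so they can fall where no peak can be called. How much this adds to the differences was not tested. Set against peaks of the pooled list outside the optimal list, where introns held 49.5%, the intron share was lower instead of higher (permutation adjusted p = 0.0056). In that background 18.1% of summits were TSS-proximal and 27.7% intergenic, so both of those directions stayed. The difference of other exons was lost against that background (permutation adjusted p = 0.290) and without replicate 3 (0.0769).

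**Figure D1:**
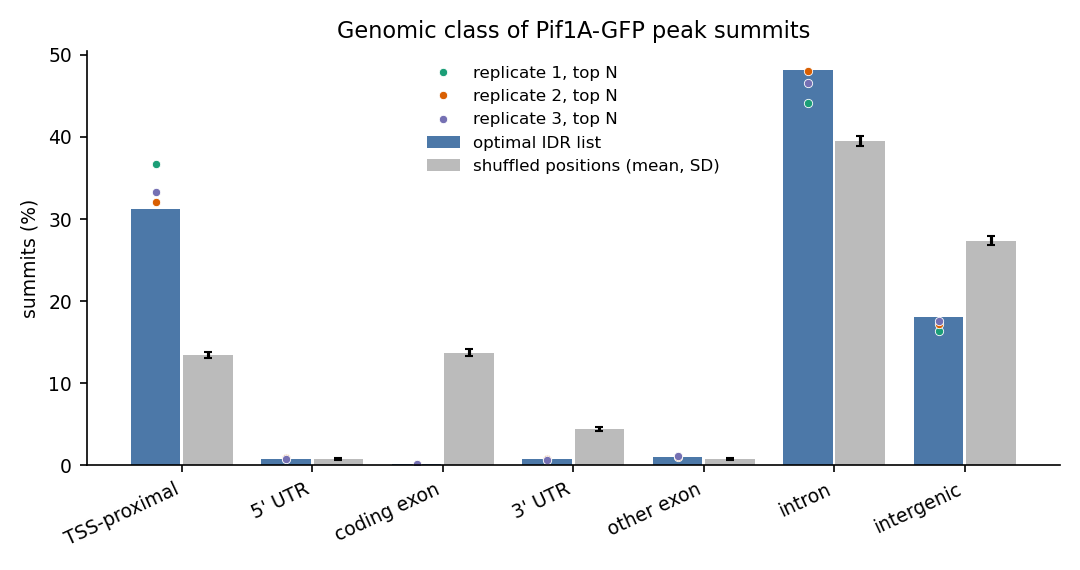
Share of summits (%) in 7 annotation classes for the optimal IDR list (blue bars), for shuffled positions (grey bars, mean with SD over 1000 shuffles) and for the 7283 highest peaks of each replicate (points). TSS-proximal summits reach 31.2% against 13.4% of shuffled positions, and coding exons 0.151% against 13.7%.

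The TSS-proximal share was highest among the highest-scoring peaks of each replicate. In 10 bins of equal size it was 36.9% ± 1.96 (SD, n = 3) in the highest bin and 14.5% ± 0.456 in the lowest, beside 13.4% of shuffled positions. This gradient is given as values, without a test. Spearman's rho across the bins was -1 in replicates 1 and 2 and -0.988 in replicate 3 and in the pooled list.

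**Figure D2:**
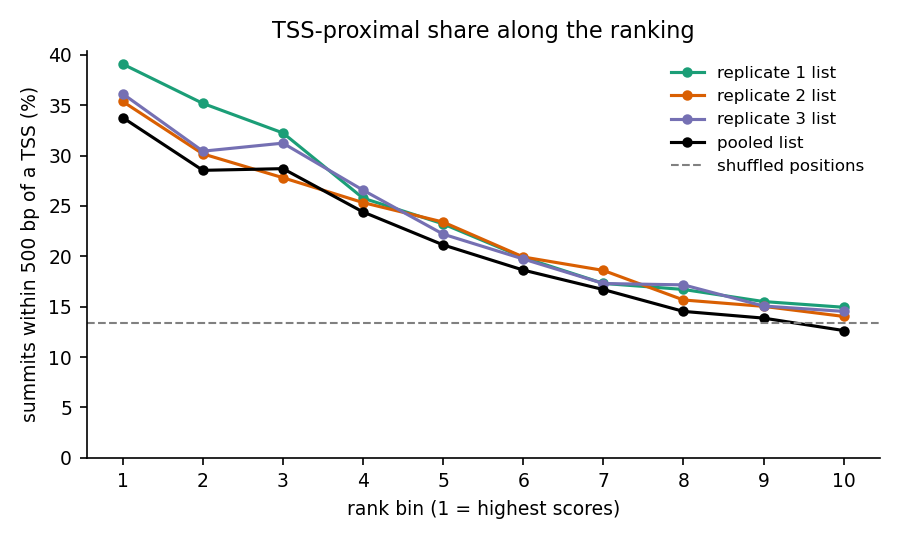
Summits within 500 bp of a TSS (%) in 10 rank bins of equal size, from the highest scores (bin 1) to the lowest (bin 10), for each replicate list and the pooled list; the dashed line marks shuffled positions. The replicates average 36.9% in bin 1 and 14.5% in bin 10.

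Peaks were spread over the major arms with modest differences in density, and were sparse on chromosome 4. Densities and tests used the full length of each arm, including any sequence where no peak can be called. How much this adds to the differences between arms was not tested. The X chromosome carried 59.2 optimal peaks per Mb (59.0 ± 3.66 in the replicates, SD, n = 3), 3L carried 57.1, 2L 56.8, 3R 52.1 and 2R 49.6. Chromosome 4 carried 24 peaks, 17.8 per Mb. No list on either build held a peak on Y, background entries included, so Y could not be tested. Against arm length, the share was higher on X (19.1% against 17.1%, exact binomial adjusted p = 1.6e-05), 3L (22.1% against 20.4%, 0.00124) and 2L (18.3% against 17.1%, 0.00783), and lower on 2R (17.2% against 18.4%, 0.0118) and 4 (0.330% against 0.980%, 4.6e-10). These backgrounds include the length of Y. Without it, an alternative chosen after seeing the data, X (exact binomial adjusted p = 0.00126), 3L (0.0416), 2R (0.000733) and 4 (2.0e-10) passed and 2L did not (18.3% against 17.6%, 0.0874). The 2L difference was lost in 7 of 10 alternatives, the 2R difference in 4 and the X difference in 2, which were the sets without replicate 1 (17.9%, exact binomial adjusted p = 0.208) and without replicate 2 (18.2%, 0.0893).

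The next comparison asked which groups of genes had peaks at their promoters. Of 13968 protein-coding genes, 1965 (14.1%) had an optimal summit within 500 bp of a TSS, and 16.2% ± 0.961 (SD, n = 3) in the replicates. Cytosolic ribosomal protein genes, a list of ecdysone response and steroid synthesis genes and genes of the Notch pathway were bound more often than other genes, and cuticle protein, chemoreceptor, replication-dependent histone and spermatogenesis genes less often. The other 13 of 20 lists did not pass the test. A gene with several TSSs has more chances to be called bound, and this test matched neither TSS number nor gene length. Median gene length was 16940 bp in the ecdysone list, 2689 bp in the Notch list and 1345 bp in the ribosomal list. In the lists bound less often it ran from 529 bp (histones) to 1900 bp (spermatogenesis).

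Cytosolic ribosomal protein genes were bound in 39 of 86 cases (45.3%, against 13.9% of other genes, odds ratio 5.15, Fisher's exact test, adjusted p = 4.5e-11). In the replicates the share was 54.3% ± 1.78 (SD, n = 3), and 31 genes were bound in all 3. The share was 29.1% without replicate 1, 30.2% without replicate 2 and 26.7% without replicate 3, sets in which 8.50% to 9.29% of all protein-coding genes were bound. The highest scores were at RpS27 (3R, score 468, summit 43 bp from its TSS), RpL24 (2L, 408, 7 bp), RpL7 (2L, 408, 41 bp) and RpL32 (3R, 388, 139 bp). These peaks ranked 614 to 885. The summits at RpS27, RpL7 and RpL32 also lay within 500 bp of a TSS of Nup37 and sisRNA:CR46364, of Ripalpha and of CG7943. Mitochondrial ribosomal protein genes did not pass the test as a list, with 11 of 73 bound (15.1%, Fisher's exact adjusted p = 0.786), yet their bound members included stronger peaks: mRpS23 (score 1919, a summit 387 bp from its TSS and nearer to that of CenG1A), mRpL41 (1216), mRpS10 (1196) and mRpL23 (1046). The last 3 summits also lay within 500 bp of a TSS of lncRNA:CR44463, Art3 and CG9004. Proteasome genes were bound in 2 of 32 cases (Rpn5 and Rpn13, exact adjusted p = 0.537), with Prosalpha1 and Prosalpha2 among those without a peak. Complex I genes were bound in 3 of 34 (ND-ASHI, score 711, ND-MNLL and ND-49, exact adjusted p = 0.773), with ND-13A and ND-13B without a peak. Each of these 5 bound promoters also had a TSS of another gene within 500 bp of the summit: Hat1 (Rpn5), CtsL1 (Rpn13), Fum1 (ND-ASHI), p115 and CG45089 (ND-MNLL) and Ephrin (ND-49).

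Genes of steroid synthesis and of the response to ecdysone, the steroid hormone of metamorphosis, were as 1 list bound in 13 of 30 cases (43.3%, against 14.0% of other genes, odds ratio 4.70, Fisher's exact test, adjusted p = 0.000365). The replicate share was 42.2% ± 5.09 (SD, n = 3). The share of the list was 30.0% to 33.3% without a replicate, by either way of matching, 23.3% with the optimal list cut at its median rank and 56.7% with a window of 1000 bp. Eip75B, a nuclear receptor gene, had the highest score (673, peak 17999605 to 17999955 on 3L, 28 bp from a TSS), followed by Eip93F (492), the receptor partner usp (192, shared with CG4313) and the coactivator gene tai (178). EcR (157), br (160), Eip74EF (162) and ftz-f1 (149) were bound too, in all 3 replicates. The steroid synthesis and metabolism genes of the list, such as dib, sad, shd, spo, spok, phtm, Npc1a and Cyp18a1, had no optimal summit at a TSS, though shd was bound in replicate 1. This subgroup was picked after its values were seen and was not tested, and list members outside it lacked a peak too.

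In the Notch list 11 of 23 genes were bound (47.8%, against 14.0%, odds ratio 5.63, Fisher's exact test, adjusted p = 0.000365), and 50.7% ± 5.02 (SD, n = 3) in the replicates. The highest scores were at numb (647, peak 9449390 to 9449779 on 2L), E(spl)m7-HLH (453), E(spl)mdelta-HLH (312, shared with CG43116) and neur (307). The neur peak had no summit within 100 bp in replicate 1. With a window of 200 bp the share was 26.1% and the list did not pass (exact adjusted p = 0.0508). It was 30.4% without replicate 1 or replicate 2 and 26.1% without replicate 3.

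Cuticle protein genes, which encode structural proteins of the exoskeleton, were bound in 1 of 122 cases (Fisher's exact adjusted p = 1.4e-06). The bound gene was Cpr72Eb (score 89.3), whose peak had no summit within 100 bp in replicates 1 and 3. Acp65Aa and Ccp84Aa had no peak. Chemoreceptor genes were bound in 1 of 179 (Gr77a, score 114; Gr10a and Gr10b had no peak; exact adjusted p = 7.0e-10). None of 111 replication-dependent histone genes was bound (exact adjusted p = 7.2e-07); these, such as His1:CG31617 and His1:CG33801, are near-identical repeated copies in which reads may not be placed uniquely, and how such reads were treated is not given in the sources used here. None of 35 spermatogenesis genes was bound, Mst77F and Mst84Da among them (exact adjusted p = 0.0333, and 0.0286 to 0.254 over the alternatives), a call that was lost in 10 of 12 alternatives.

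**Figure D3:**
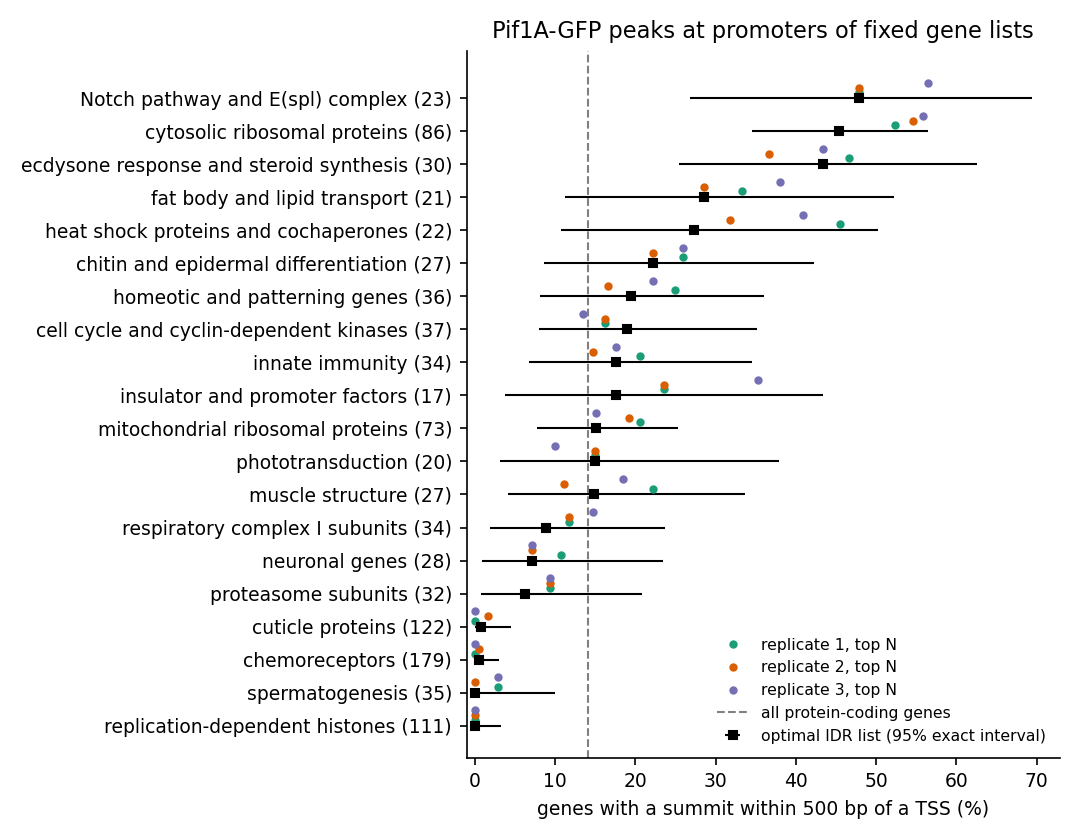
Genes with a summit within 500 bp of a TSS (%) for 20 gene lists (number of genes in brackets): optimal IDR list (squares, exact 95% binomial interval) and the 7283 highest peaks of each replicate (points, drawn slightly above). The dashed line is the 14.1% of all protein-coding genes; the Notch, ribosomal protein and ecdysone lists lie between 43.3% and 47.8%.

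Among lists that did not pass (Fisher's exact adjusted p from 0.252 to 0.786), single members had strong peaks. Others, such as Zasp52 (89.2) and Syt1 (87.8), lay near the lowest score of the optimal list (87.7). No summit lay within 100 bp in replicate 2 for Cdk12 and bmm, or in replicate 3 for Cdk1, rdgB and Syt1. Heat shock genes were bound in 6 of 22 cases (27.3%), with Hsp27 at score 1851, Hsp83 at 623, Hsp26 at 563 and stv at 394. Fat body and lipid genes were bound in 6 of 21 (28.6%), led by Lpin (1119), Mtp (309), bmm (213) and Desat1 (164). Chitin and epidermal genes were bound in 6 of 27 (22.2%), led by Cht7 (410), sha (225), grh (225) and kkv (135). Homeotic and patterning genes were bound in 7 of 36 (19.4%), led by hb (469), Dll (197), so (154) and wg (118). Cell cycle genes were bound in 7 of 37 (18.9%), led by Cdk12 (204), fzr (195), CycE (176) and Cdk1 (131). Insulator and promoter factor genes were bound in 3 of 17 (17.6%): Chro (1991, in a promoter region shared with Ssl1), Trl (285) and BEAF-32 (215). Innate immunity genes were bound in 6 of 34 (17.6%), led by imd (987), cact (427), Dif (167) and dl (137). Phototransduction genes were bound in 3 of 20 (15.0%): rdgC (467), norpA (179) and rdgB (110). Muscle genes were bound in 4 of 27 (14.8%): Msp300 (708), sls (290), Tm1 (132) and Zasp52 (89.2). Neuronal genes were bound in 2 of 28 (7.14%), elav (868) and Syt1 (87.8), with Appl and Cadps without a peak. Summits with a TSS of a second gene within 500 bp were those at imd (Dp1), Cdk12 (SAK), Cdk1 (mRpS7), bmm (Tdrd3), grh (asRNA:CR45270), BEAF-32 (asRNA:CR42254) and elav (lncRNA:enrr). Leaving out a replicate, by either way of matching, gave 13.6% to 22.7% for heat shock genes, 14.3% to 28.6% for fat body genes, 11.1% to 22.2% for chitin genes, 8.33% to 13.9% for homeotic genes and 8.11% to 13.5% for cell cycle genes, beside 8.50% to 10.5% of all protein-coding genes. In the same sets insulator genes were at 11.8% to 17.6%, innate immunity genes at 11.8% to 14.7%, phototransduction genes at 10% to 15.0%, muscle genes at 11.1% to 14.8% and neuronal genes at 3.57% throughout, and of the lists above, mitochondrial ribosomal genes at 10.96% to 13.7%, proteasome genes at 6.25% and complex I genes at 5.88%.

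Noncoding genes were bound less often than protein-coding genes in 4 of 6 classes by Fisher's exact test. The annotated start of a noncoding transcript need not be a promoter, and the number of TSSs per gene was not matched. These differences may therefore partly reflect the annotation. The shares were 3.72% of 269 snoRNA genes (exact adjusted p = 2.1e-07), 5.38% of 260 miRNA genes (2.4e-05), 11.4% of 1987 lncRNA genes (0.0014) and none of 99 rRNA genes (1.7e-06), the last being repeated copies. Leaving out a replicate gave 1.12% to 1.86% for snoRNA genes, 2.31% to 2.69% for miRNA genes and 5.94% to 6.89% for lncRNA genes, beside 8.50% to 9.29% of protein-coding genes, and kept these 3 calls. The shares of tRNA genes (34 of 290, 11.7%) and snRNA genes (2 of 32) did not pass the test against 14.1% (exact adjusted p = 0.306 for both), and were 5.86% to 7.93% and 3.13% to 6.25% without a replicate. The lncRNA difference was lost with a window of 1000 bp (18.5%, exact adjusted p = 0.309). The tRNA genes were lower with nearest-TSS assignment (5.86%, exact adjusted p = 0.00169) and with a window of 200 bp (5.52%, 0.0360).

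The other promoters among the 20 highest optimal peaks found in all 3 replicates were those of CG18549 (score 2025), Hsp27, lncRNA:CR31044 (1735), CG13921 (1667) and the pair CG3437 and CG3552 (1609), beside Ssl1 and Chro and the pair CenG1A and mRpS23 named above. Of the optimal peaks, 3258 (44.7%) had a summit over 2000 bp from every TSS. The highest of these lay between genes on 2R (13035075 to 13035565, score 2065), 11918 bp from the nearest TSS, that of CG13323. The next were in an intron of dnr1 (2R, score 1634) and between genes near CG31668 (2L, 1634). Introns of CG12769 (1461), CG32486 (1388), the ecdysone-responsive nuclear receptor gene Hr4 (X, 1951733 to 1952097, score 1267), Raf (1064) and babos (1023) held others, and 2 more lay between genes nearest to CG43245 (1247) and pxb (1133).

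At the locus of the tagged gene itself, the strongest peak lay in an intron of Pif1A (3R, 8789075 to 8789358, score 669), 3342 bp from the nearest TSS. It ranked 255 in the optimal list and 230, 405 and 215 in replicates 1, 2 and 3. A second peak (8792587 to 8793010, score 236) lay 252 bp from a TSS that the annotation gives to Pif1A and the overlapping gene Pif1B. The flies carry a tagged transgene, which can add copies of this locus, so these 2 peaks need not mark binding. Copy number was not tested. Eip63E had a promoter peak near the end of the list (score 89.7, rank 7078), which had no summit within 100 bp in replicates 1 and 2 and ranked 8286 in replicate 3. Other summits made Eip63E bound in the 7283 highest peaks of replicates 2 and 3, while CycY, the gene of a cyclin partner of Eip63E, had none. Inside Eip63E (94.8 kb), 7 optimal summits lay over 500 bp from every TSS, and CycY held no such summit.

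Sequence at the summits was AT-rich. GC content was 34.6% within 50 bp of optimal summits and 35.2% ± 0.410 (SD, n = 3) in the replicates, against 43.5% at 400 bp to the right and 42.1% over the arms. Of 20 motifs, 9 differed between the summit and the window 400 bp to the left by the exact McNemar test. By that exact test, the A tract (11.96% of summits against 6.15%, adjusted p = 1.7e-33), the TATA box (3.38% against 1.76%, 6.4e-09), the GATA site (3.58% against 2.43%, 0.000139) and the Su(Hw) core (0.989% against 0.604%, 0.0247) were more frequent at summits. The CA repeat (1.77% against 4.06%, 5.8e-16), the CAGCTG E-box (3.02% against 4.74%, 3.6e-07), the CTCF core (1.62% against 2.62%, 0.000119), the CACGTG E-box (0.673% against 1.37%, 0.000119) and the Pho core (3.41% against 4.59%, 0.000743) were less frequent. Against dinucleotide-shuffled copies of the same windows the TATA box (3.49% in shuffled copies, exact adjusted p = 0.786), the GATA site (3.13%, 0.178) and the Pho core (3.69%, 0.434) no longer passed, while the TCT initiator (14.1% against 11.5%, 6.8e-07), the GAGA element (2.69% against 1.07%, 1.4e-15), the DRE (0.522% against 0.0687%, 8.3e-07) and M1BP motif 1 (0.275% against 0.0137%, 5.2e-05) were more frequent. None of these 4 passed against the window to the left, where the GAGA element was found in 3.05%. The A tract (8.58% in shuffled copies, 5.7e-15) and the Su(Hw) core (0.316%, 9.9e-07) were more frequent against both controls, though the Su(Hw) difference was lost in 4 of 9 alternatives. The CACGTG E-box was less frequent against both (1.06% in shuffled copies, exact adjusted p = 0.030), with its difference lost in 2 of 9 alternatives. The direction turned for the CAGCTG E-box (1.48% in shuffled copies), the CTCF core (0.947%) and the CA repeat (0.343%), which were more frequent at summits than in shuffled copies. Both controls may favour the A tract. The window to the left had a GC content of 44.0%, and shuffling can break up runs of a single base. Their joint result therefore does not single out A tracts as a feature of summits.

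**Figure D4:**
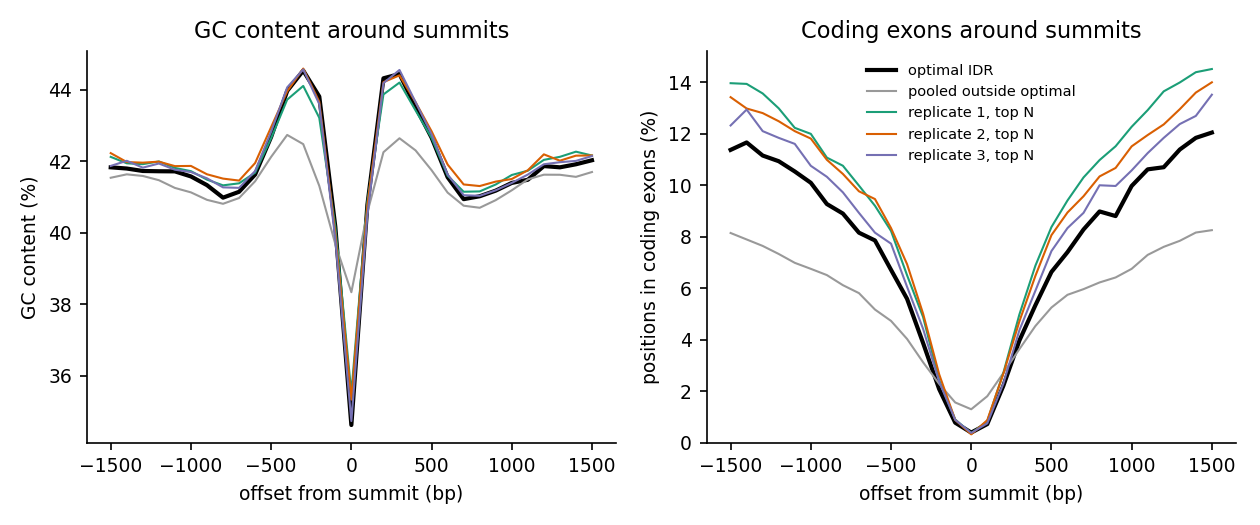
GC content (%, left) and share of positions in coding exons (%, right) by offset from the summit (bp), for the optimal IDR list, pooled peaks outside it and the 7283 highest peaks of each replicate. GC content is 34.6% at optimal summits and 38.3% at summits of pooled peaks outside the list.

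The lists on the older dm3 build were similar in size. The optimal list had 7466 peaks on dm3 and 7283 on dm6, with 1439 and 1393 on X, 1649 and 1606 on 3L, 1696 and 1671 on 3R, 1363 and 1335 on 2L, 1286 and 1254 on 2R, and 27 and 24 on chromosome 4. No positions were converted between builds.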

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

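Peaks on sequence outside the chromosome arms, which were left out of every comparison but the overlap of replicates, were found in some lists; both tests of the mitochondrial pattern were chosen after the result was seen. Replicate 1 listed 16 mitochondrial peaks on dm6, more than the limit of 3 peaks set for such sequence, while replicates 2 and 3 and the pooled list had 0. Of the 16, 11 were among its 7283 highest peaks and so entered that overlap, and the highest ranked 18 with a score of 506. On dm3 the same replicate listed 4 mitochondrial peaks, replicate 3 listed 2 (best rank 18907) and the pooled list 2 (best rank 16391). The heterochromatic and unplaced sequences of dm3 held 66 peaks in replicate 1, 56 in replicate 2, 49 in replicate 3, 57 in the pooled list and 6 in the optimal list.

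The best mitochondrial peak of replicate 1 ranked 18 on dm6 and 11296 on dm3, in lists of 30000 each. A candidate explanation for this difference between builds is the mitochondrial reference or the alignment used for each. Scores of different lists may not share a scale; as deposited, the highest mitochondrial score was 24.2 times as high on dm6 as on dm3, while the highest score on the arms differed by 0.0465%. Since the builds may place mitochondrial reads differently, the rank on dm3 does not decide whether the library of replicate 1 held more mitochondrial DNA. Why replicates 2 and 3 show no such peaks on dm6 stays open, and no biological explanation was tested. The dm6 list of replicate 1 also had a lower highest −log10 q-value, 2.61, than replicates 2 (3.85) and 3 (3.89). On dm3 that of replicate 1 was 3.70. Whether this bears on the mitochondrial peaks was not tested.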

How the results depend on the processing

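The alternatives that left out a replicate by summits within 100 bp, or Y from the arm lengths, were chosen after seeing the data; the others were planned. Taking the highest peaks of the pooled list in place of the optimal list changed nothing, because the lists hold the same peaks, so that alternative is void; it is included in the counts below. The shared share of replicate peaks stayed above its shuffles in all 8 alternatives (65.3% to 77.0%), and the TSS-proximal share above its background in all 11 (18.4% with 200 bp to 41.9% with 1000 bp). Optimal peaks found in all 3 replicates numbered 3283, but 5417 among the 2N highest peaks and 5718 in the whole replicate lists. Leaving out a replicate gave 3856 to 4103 by 50% overlap, and 4620 to 4877 with summits within 100 bp, where all 3 replicates gave 4087. The number of arms that differed was 6, the void test of Y included, 4 without the length of Y, and ranged from 3 (without replicate 2) to 5 when a replicate was left out; fewer peaks enter those tests. The number of motifs that differed was 9, and 4 both for TSS-proximal peaks alone and against TSS-proximal peaks outside the optimal list; the cause was not tested, and fewer peaks enter both. It was 13 in windows reaching 100 bp from the summit and 9 or 10 in the other alternatives. Spearman's rho of the pooled rank gradient was -0.976 with 200 bp and -1 with 1000 bp. Directions reversed in 4 cases. Introns, at 48.1%, were below the 49.5% of peaks outside the optimal list. Against dinucleotide-shuffled copies the CAGCTG E-box (3.02% against 1.48%), the CTCF core (1.62% against 0.947%) and the CA repeat (1.77% against 0.343%) were more frequent at summits. The cause of these 4 reversals was not tested. Past the threshold were 5 to 7 gene lists over the alternatives, beside 7, 3 to 5 noncoding classes, beside 4, and 5 to 6 annotation classes, beside 6. The ribosomal protein, ecdysone, histone, cuticle and chemoreceptor lists passed in all 12 alternatives, the Notch list in 11 (not with 200 bp, 26.1%) and the spermatogenesis list in 2. Its bound share was 2.86% with 1000 bp and 0% in the other alternatives, and the sets without a replicate hold fewer peaks. In those sets, by either way of matching, the ribosomal share was 26.7% to 39.5%, the ecdysone list share 30.0% to 33.3%, the Notch share 26.1% to 43.5%, the share of all protein-coding genes 8.50% to 10.5%, the coding exon share 0.0778% to 0.103% and the chromosome 4 share 0.219% to 0.295%. No paired analysis was possible because there is 1 group. Depth is unknown, and its effect could not be examined.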

Other observations

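The tests of gene bodies, of coding exons and of ribosomal protein promoters were chosen after the main results were seen, but the outcomes that would count for or against base composition were set before the GC-matched and promoter-matched draws were made. Optimal summits inside protein-coding genes and over 500 bp from every TSS were counted per gene. The genes with most were kirre, an immunoglobulin-family adhesion gene (30 peaks over 394 kb), sbb (28 over 79.1 kb), Snoo (24 over 93.0 kb) and Tet (24 over 93.0 kb). In the highest peaks of the replicates the order differed: sbb had 30 in each, kirre 27.0 ± 3.61, Tet 23.0 ± 2.00 and Snoo 21.7 ± 3.21 (SD, n = 3). Mnt, a gene of the Max network of transcription factors, was the densest of the 12 genes with most peaks, at 5.69 peaks per 10 kb (17 peaks). Eip75B held 13 and EcR 8.

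Neuronal genes, many of them long, held few such peaks. Of 28 genes, 3 (10.7%; elav, fne and Shal) had 1, against 44.7% in lists matched on gene length (permutation over 10000 lists, p = 0.0002, the smallest they can give, adjusted p = 0.0040 over 20 lists). In the replicates the share was 8.33% ± 2.06 (SD, n = 3). Snap25, a gene of 225 kb, and Sh, of 139 kb, had none. The lists were matched on length only, not on location or on sequence where peaks can be called. Cadps, for example, lies on chromosome 4, where peaks were sparse (17.8 per Mb). Genes of ecdysone response and steroid synthesis had internal peaks in 16 of 30 cases (53.3% against 35.4%, permutation p = 0.0188), which did not pass adjustment (0.188). The other 18 lists did not pass either.

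Few summits lay in coding exons, and base composition was weighed first, since summits are AT-rich and coding exons are not. Random positions matched on GC content within 50 bp lay in coding exons in 5.32% ± 0.238 of cases (SD over 100 draws). The shares were 0.151% of optimal summits and 13.7% of unmatched positions. GC content within 50 bp may therefore account for part of the difference but not all of it. Other aspects of base composition, such as the GC profile around the summit, were not matched. A property shared by every call, such as how peaks are called or which sequence is recovered, is a candidate explanation, because pooled peaks outside the optimal list were in coding exons in only 0.867% of cases. No biological explanation was tested.

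Ribosomal protein genes were bound more often than other genes. If every housekeeping promoter were captured alike, the mitochondrial ribosomal, proteasome and complex I lists would be high too. Their combined odds ratio was 0.793 (95% interval 0.438 to 1.34), below the interval of the ribosomal list (3.27 to 8.07). This argues against that explanation for these 3 lists. Their shares were already known when the comparison was set, so it is not an independent test. Promoter GC content and the number of genes with a neighbouring TSS are unlikely to be the whole cause: lists matched on both were bound in 14.9% of cases (central 95%, 8.14% to 22.1%) against 45.3%. Level of transcription stays open, since no expression values were used here, and no biological explanation was tested.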
